A study of Drosophila melanogaster with 90 samples.

How the data were processed

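PolyA RNA from ovaries of Drosophila melanogaster females was sequenced in 90 libraries, 3 for each of 30 genotypes. Per the labels, 15 ovaries were dissected for each sample from females aged 4 to 5 days and raised at 25 °C, and 200 ng of total RNA with 10 pg of ERCC spike-in RNA (pool 78A or 78B) went into each stranded library. The submitters' processing notes name CASAVA 1.8.2, HISAT2 2.0.5 and HTSeq 0.7.2, and the series text gives 50 bp single-end reads mapped to release 6.21 of the genome. The deposited values are counts of reads per gene, per transposable element family and per ERCC spike-in, 1 column per library, with no normalisation. Each library has 17741 entries, of which 17493 were genes, 147 transposable element families, 96 ERCC spike-ins and 5 counting summaries. The 5 summaries, which hold reads not assigned to any feature, took 12.55% to 63.09% of the reads of a library (median 18.495%) and were left out of the tests. How reads that map to several copies were counted is not stated, so families of near-identical copies (transposable elements, Hsp70 genes, histones, Mst84D genes) may share reads.

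Symbols and positions came from a release 6 annotation (BDGP6 assembly), in which 17366 of the genes were found, sov by its symbol and the others by identifier. The other 127 identifiers were tested under their identifier alone. No pair of the 90 libraries had identical counts. Depth, as the sum of gene counts, ran from 2110 to 13164806 with a median of 4346724.5, and 6 libraries held under 2000000. A count of 0 allows a level of up to 3 counts, and folds against a group in which every library had 0 counts are given as lower bounds against 3 counts over the group. Such bounds cover counting error only.

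Genotypes were grouped by the submitters' analysis groups and fertility labels into controls (10 genotypes), sterile sov mutants (7), fertile sov mutants (7), mCherry RNAi (3) and sov RNAi (3). The class comparisons used counts summed over the 3 libraries of each genotype, so that the genotype was the replicate, in a single fit of the 24 mutant and control genotypes. Alleles recur in several genotypes of a class, so these genotypes are not fully independent. The RNAi comparisons used all 18 RNAi libraries in a single fit with 6 groups, from which the effect of each driver and the difference between the nos and tj effects were taken. The deficiency heterozygote was compared with w1118/w1118 over 3 libraries each, and 6 pairs of genotypes with the alleles written in opposite order were tested at once over 36 libraries. The RNAi, deficiency and allele-order tests measure differences against the spread between the libraries of a genotype.

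Genes were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) after TMM scaling and the default filter of filterByExpr. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum, and changes over 2-fold were counted as well. Fold changes are on the log2 scale with their standard error. Levels of sov are given as CPM, the library-size-scaled count that edgeR computes from TMM-scaled library sizes, and genotype means of log2(CPM + 1) were compared between classes by exact two-sided permutation tests, as were log2 shares of transposable element counts and, chosen after the data were seen, log2 element counts per ERCC count. Values per genotype came from a fit with 1 coefficient per genotype, each set against the mean of the 10 controls, and no genes were counted there. Overlaps of calls were tested by one-sided Fisher's exact tests.

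The gene lists covered the piRNA pathway, heterochromatin proteins, transposable elements, early germline, oocyte and maternal transcripts, yolk and yolk uptake, vitelline membrane, chorion, ecdysone response, ovarian soma and follicle cells, testis-enriched genes, sex determination, apoptosis and stress, heat shock, antimicrobial and immune genes, antiviral RNAi, JAK-STAT and BMP signalling, germ cell cycle and meiosis, replication and mitosis, ribosomal proteins, replication-dependent histones, oxidative phosphorylation, genetic markers of the stocks, and markers of muscle, fat body, gut, neurons, hemocytes and basement membrane, and sperm storage and oviduct. Chromosome sets were the genes on X, 2L, 2R, 3L, 3R, 4 and Y and those in pericentromeric blocks (2L beyond 22 Mb, 2R up to 5.4 Mb, 3L beyond 23 Mb, 3R up to 4.5 Mb and X beyond 22 Mb). Each list was tested with camera (limma 3.58.1) against all other genes with a preset correlation between genes of 0.01, adjusted over all lists, and also with an estimated correlation and with fry. Counts adjusted over the list alone are given beside those adjusted over all genes. Several symbols in the lists (nos, phm and punt among them) had no entry under that name and were left out.

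The comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined, apart from the fits without the libraries under 100000 counts and without KG00226/w1118 replicate 3 and some tests of explanations, which were chosen after the data were seen. The rule takes sov, up to 3 members of each list with the smallest adjusted p, and the 5 rising and 5 falling genes with the largest change among those called, with a mean of at least 10 CPM in the higher group and no overlap between groups. For the other comparisons it takes 3 rising and 3 falling genes, for the deficiency also every tested gene within 50 kb of sov, and for allele order the 5 genes with the smallest p. Names given in the text for the genes shared by all 3 drivers were chosen after their values were seen.

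The tests were tried on simulated data in which 196 to 200 genes were changed, for allele order in 1 of the 6 pairs. For sterile mutants against controls the test recovered 77% of 2-fold and 97% of 4-fold changes, and 3.87% of its calls were unchanged genes. For da-Gal4 these figures were 80%, 95% and 3.85%, for the nos and tj difference 64.3%, 94.9% and 3.7%, for the deficiency 90%, 99% and 4.57%, and for allele order 79%, 92.9% and 5.52%. In simulated data camera called a shifted list (adjusted p = 4.97e-80) and 0 of 100 random lists. The simulated genes were drawn independently of each other, so this trial does not cover lists of genes that vary together.

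Alternatives were DESeq2 size factors, upper-quartile scaling, TMM without the yolk and eggshell lists, no filter on low counts, DESeq2 1.42.0's Wald test, limma voom with the genotype as a random effect, libraries as the unit, the replicate number as a block, the ERCC pool as a covariate, fits of 1 driver alone, and fits without each replicate, library or genotype. The replicate numbers did not pair the libraries: the residuals of libraries with the same number had a mean correlation of 0.0173 over 63 mutant and control libraries and -0.00721 over the 18 RNAi libraries. Tables were handled in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with matplotlib 3.10.9.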

Results

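Ovarian RNA was measured by stranded RNA sequencing in 90 libraries from females that carried alleles of sov or expressed a hairpin against it. The gene sov (small ovary, FBgn0029899) lies on the X at 6756322 to 6770712 on the plus strand (BDGP6, release 6) and encodes a nuclear zinc-finger protein. The 30 genotypes had 3 libraries each. The 10 control genotypes (30 libraries) carried w1118 with or without a single sov allele. No mutant genotype carried w1118, so a difference between mutants and controls includes any difference in stock background. The 7 sterile mutant genotypes (21 libraries) were Dfsov/KG00226, Dfsov/sov2, NP6070/NP6070, sovEA42/KG00226, sovEA42/sov2, sovML150/KG00226 and sovML150/sov2, where Dfsov is a deficiency that removes sov and KG00226 and NP6070 are transposon insertions. The 7 fertile mutant genotypes (21 libraries) were KG00226/KG00226 and the 6 genotypes that pair KG00226, NP6070 and sov2 with each other in either written order. The remaining 18 libraries came from RNAi with the drivers da-Gal4 (ubiquitous), nos-Gal4 (germline) and tj-Gal4 (ovarian soma), each with a hairpin against sov (sterile females) or against mCherry (fertile females). The hairpins against sov and mCherry sit at different genomic sites and in different stocks, so a sov RNAi effect includes any difference between those stocks.

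Total gene counts per library ran from 2110 to 13164806, with a median of 4346724.5. The 3 libraries under 100000 counts were sov2/w1118 replicate 1 (2110 counts), Dfsov/sov2 replicate 3 (16486 counts) and sovML150/KG00226 replicate 2 (49795 counts). The other libraries above 2000000 counts began at 2361331.

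The level of sov mRNA was measured first, to ask how far each genotype lowered the transcript itself. In w1118/w1118 ovaries sov stood at 149 ± 9.72 CPM (TMM-scaled reads; SD, n = 3). It fell with 1 copy of the deficiency, to 99.8 ± 8.76 CPM in Dfsov/w1118 (log2 change -0.57 ± 0.09 SE, edgeR adjusted p = 0.00504), and was lowest of all genotypes in Dfsov/KG00226, at 84.0 ± 4.93 CPM. By CPM, a share of the library, several sterile genotypes stood above w1118/w1118. Among them were sovEA42/sov2 at 275 ± 33.6 CPM and sovML150/sov2 at 340 ± 9.45 CPM (n = 3 each). Relative to ERCC counts, a scale chosen after the data were seen, sovML150/sov2 was lower and sovEA42/sov2 overlapped w1118/w1118. The sovML150/sov2 libraries held 313, 809 and 2664 sov counts beside 987, 2825 and 6488 ERCC counts. Those of w1118/w1118 held 1126, 666 and 917 beside 1337, 1427 and 940. With da-Gal4, sov fell from 181 ± 24.3 to 129 ± 7.71 CPM (log2 change -0.49 ± 0.12, adjusted p = 0.00634). With nos-Gal4 it stood at 163 ± 22.9 CPM with the mCherry hairpin and 169 ± 26.9 CPM with the sov hairpin (log2 change 0.06 ± 0.12, adjusted p = 0.907). With tj-Gal4 it rose by CPM, from 161 ± 7.63 to 226 ± 13.5 CPM (log2 change 0.50 ± 0.11, adjusted p = 0.00501). Relative to ERCC counts sov was lower with the sov hairpin in every tj-Gal4 library. The sov hairpin libraries held 1256, 2121 and 1754 sov counts beside 1979, 2521 and 2426 ERCC counts. The mCherry libraries held 677, 492 and 853 beside 618, 289 and 723. Over genotype means, the difference between sterile mutants and controls was 0.47 on the log2 scale (exact two-sided permutation p = 0.249, adjusted over 3 comparisons 0.374), that between fertile mutants and controls was 0.46 (exact permutation p = 0.152), and that between sterile and fertile mutants was 0.01 (exact permutation p = 0.971). The control mean includes sov2/w1118 replicate 1, whose 2110 counts held none for sov. Without the 3 libraries under 100000 counts these differences were 0.34 (exact permutation p = 0.197), 0.22 (exact permutation p = 0.148) and 0.12 (exact permutation p = 0.702).

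**Figure D1:**
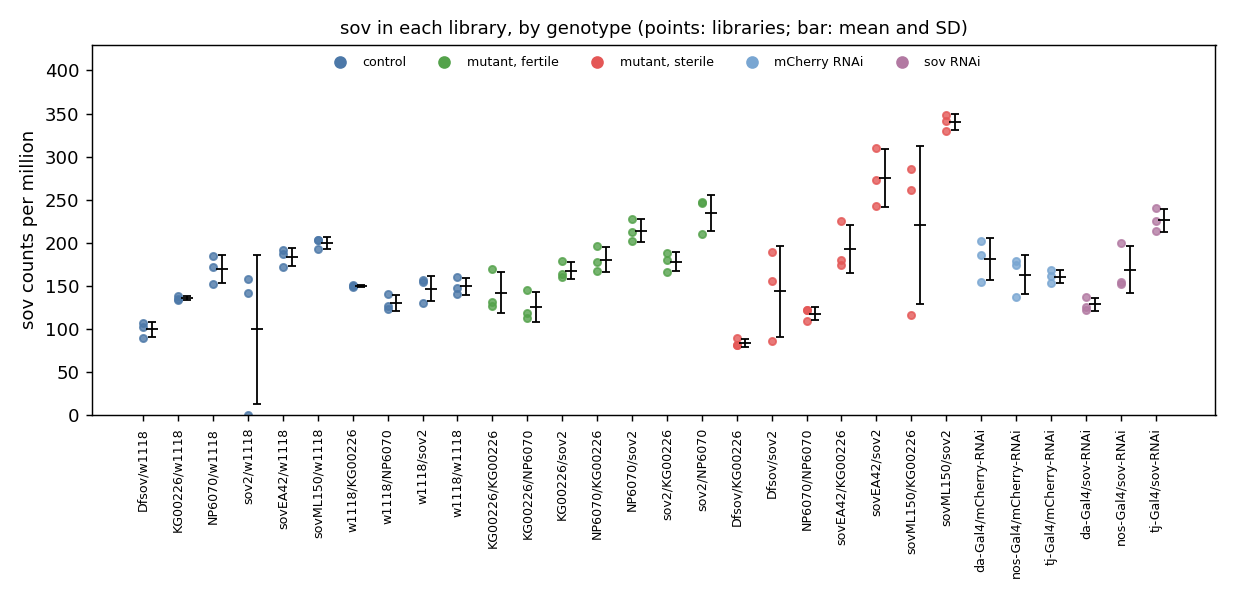
Level of sov mRNA in CPM for every library, by genotype; points are libraries, bars the mean with SD over 3 libraries. Dfsov/KG00226 has the lowest genotype mean (84.0 CPM) and sovML150/sov2 the highest (340 CPM); the point at 0 is the sov2/w1118 library with 2110 gene counts.

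Transposable element RNA was the clearest difference between mutant and control ovaries. It took 0.0328% of gene and element counts in w1118/w1118 and 0.0328% to 0.0611% in 8 of the 10 control genotypes. It took 0.593% (sovML150/sov2) to 1.89% (Dfsov/KG00226) in the 7 sterile genotypes and 0.136% (KG00226/sov2) to 1.44% (NP6070/KG00226) in the 7 fertile mutant genotypes. The other two control genotypes had means raised by 1 library each, at 0.451% in KG00226/w1118 replicate 3 and at 0.706% in the sov2/w1118 library of 2110 counts. The log2 share was higher than in controls by 4.22 in sterile and by 3.20 in fertile mutants, both with an exact two-sided permutation p of 5.14e-05, the smallest the 7 and 10 genotypes can give. Between sterile and fertile mutants the difference was 1.02 (exact permutation p = 0.0711), which did not pass. Per ERCC count, a scale chosen after the data were seen, element counts were higher than in controls by 2.80 in sterile mutants (exact permutation p = 0.000103) and by 3.64 in fertile mutants (exact permutation p = 5.14e-05), and the difference between sterile and fertile mutants was -0.85 (exact permutation p = 0.237). With RNAi the share was 0.0443% ± 0.00217 with mCherry and 1.24% ± 0.295 with sov under da-Gal4, 0.0474% ± 0.00526 and 0.921% ± 0.107 under nos-Gal4, and 0.0391% ± 0.00917 and 0.13% ± 0.0456 under tj-Gal4 (SD, n = 3 each). Per 100 ERCC counts the tj-Gal4 libraries overlapped, at 268.7 to 659.5 element counts with sov and 231.7 to 373 with mCherry. On that scale the libraries of da-Gal4 and of nos-Gal4 were separated by hairpin.

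**Figure D2:**
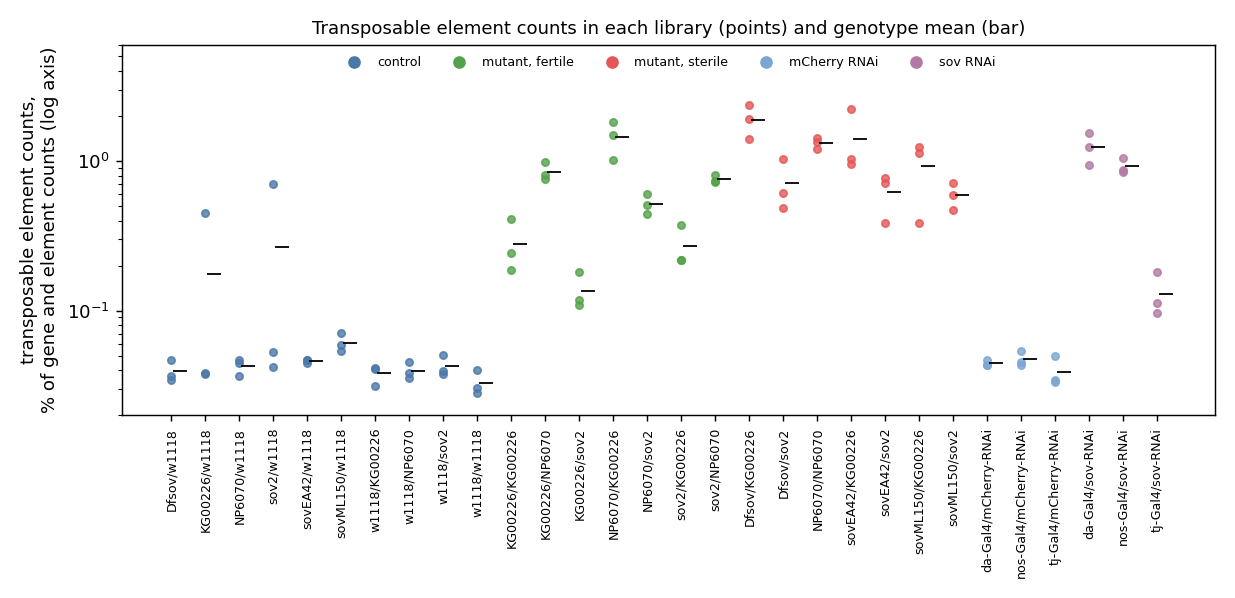
Transposable element counts as a percent of gene and element counts in every library (log axis), by genotype; points are libraries and bars genotype means over 3 libraries. Sterile genotypes have means of 0.593% to 1.89%, and w1118/w1118 has 0.0328%.

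Sterile mutants were compared with controls to ask what differs in ovaries that cannot make progeny. Of 117 tested transposable element families, 110 rose in the 7 sterile genotypes against the 10 controls (111 adjusted over the list alone), with a median log2 change of 3.21. Rises named by the rule for naming genes included the telomeric retrotransposons HETA (6.64 ± 0.76 SE, adjusted p = 4.34e-07) and TAHRE (6.59 ± 0.64, adjusted p = 5.91e-08). They also included the Gypsy-class elements Gypsy (6.35 ± 0.78, adjusted p = 8.59e-07), ZAM (5.16 ± 0.34, adjusted p = 1.65e-10) and Gypsy1 (4.18 ± 0.23, adjusted p = 1.34e-11). By genotype, the telomeric element TART stood at 5.31 to 7.67 in sterile mutants. Gypsy stood at 2.52 in NP6070/NP6070 and at 5.21 to 7.98 in the other sterile genotypes. In fertile mutants Gypsy stood at 5.14 to 6.36 with sov2 and at 1.45 to 2.33 without it. The list's median was positive in 7 of 7 sterile genotypes (2.80 to 3.71). The list passed camera (adjusted p = 2.32e-73; adjusted p = 0.000794 with an estimated correlation). In all, 3750 of 8449 tested genes and elements changed, 2077 up and 1673 down, with 1130 up and 226 down over 2-fold.

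Eggshell and yolk genes fell in the sterile mutants, and markers of muscle and hemocytes rose in the same ovaries. All 17 tested chorion genes, which build the outer eggshell, fell (17 adjusted over the list alone; median -2.82, camera adjusted p = 2.48e-10, adjusted p = 0.312 with an estimated correlation), with Cp7Fa at -3.14 ± 0.69 (adjusted p = 0.000823) and yellow-g2 at -2.87 ± 0.63. Of 13 vitelline membrane genes 11 fell (13 adjusted over the list alone; median -1.45, adjusted p = 4.34e-05, adjusted p = 0.312 with an estimated correlation), among them the cadherin Cad74A at -1.91 ± 0.44. All 4 yolk genes fell (4 adjusted over the list alone; median -1.55, adjusted p = 0.00288, adjusted p = 0.312 with an estimated correlation), with the yolk protein gene Yp2 at -1.77 ± 0.36. In the same comparison 20 of 20 muscle genes rose (20 adjusted over the list alone; median 3.87, adjusted p = 3.35e-16, adjusted p = 0.312 with an estimated correlation), with the myosin heavy chain gene Mhc at 4.56 ± 0.48 (adjusted p = 1.53e-07). Of 11 hemocyte and basement membrane genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 1.14, adjusted p = 0.00288, adjusted p = 0.453 with an estimated correlation), with Pxn at 5.65 ± 0.59 and Hml, a hemocyte marker, at 5.62 ± 0.59. The 7 sterile genotypes spread widely, from -7.16 to -0.72 for the chorion median and from 0.04 to 5.10 for the muscle median. The hemocyte median ran from -0.38 (NP6070/NP6070) to 6.17 (Dfsov/sov2). Medians by genotype come from a separate fit with its own filter, so their members can differ from those of the class comparison. NP6070/NP6070 kept muscle markers near control levels (median 0.04) with transposable elements raised (median 3.23).

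Other markers outside the egg chamber also differed between sterile mutants and controls. Of 8 neuronal genes 7 rose (7 adjusted over the list alone; median 1.28, adjusted p = 7.76e-05, adjusted p = 0.0895 with an estimated correlation), with the synaptic gene Snap25 at 4.01 ± 0.49. By genotype Snap25 was higher in fertile mutants as well, at 1.86 to 4.73 beside 2.78 to 5.055 in sterile mutants. Of 11 fat body genes 4 rose (4 adjusted over the list alone; median 0.10, adjusted p = 0.501), led by the larval serum protein gene Lsp2 at 7.19 ± 0.98 (adjusted p = 2.96e-06). Of 9 genes of sperm storage organs and oviduct 4 rose and 1 fell (the same numbers adjusted over the list alone; median 0.56, adjusted p = 0.121), with the Hox gene abd-A at 3.31. None of 25 gut genes had enough counts to be tested. Of 5 stock markers only w rose, at 2.53 ± 1.01 (adjusted p = 0.0445; 0 adjusted over the list alone; list median 0.46, adjusted p = 0.673). NP6070 carries a w+ transgene, and without NP6070/NP6070 the value for w was -0.77 (adjusted p = 0.463). It also failed the threshold, at adjusted p of up to 0.068, without any 1 of Dfsov/w1118, KG00226/w1118, sov2/NP6070, sovEA42/w1118, sovML150/w1118, w1118/KG00226, w1118/sov2 and w1118/w1118.

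The next 6 lists had medians below 0 in sterile mutants. This held in every sterile genotype for oocyte and maternal genes (-0.62 to -0.08) and for ribosomal protein genes (-0.57 to -0.16). It did not for the others (0.08 for replication in Dfsov/KG00226 and 0.03 for oxidative phosphorylation in NP6070/NP6070, for example). Of 26 oocyte and maternal genes 17 fell (18 adjusted over the list alone; median -0.31, adjusted p = 3.76e-05, adjusted p = 0.312 with an estimated correlation), including the anterior determinant bcd at -0.47 ± 0.10. Of 21 replication and mitosis genes 14 fell (15 adjusted over the list alone; median -0.34, adjusted p = 3.76e-05, adjusted p = 0.442 with an estimated correlation), with the licensing factor gene dup at -0.58. Of 81 ribosomal protein genes 60 fell and 2 rose (68 and 2 adjusted over the list alone; median -0.37, adjusted p = 3.05e-10, adjusted p = 0.486 with an estimated correlation), and the risers were RpS19b (3.19 ± 0.35) and RpS10a (3.82 ± 0.72). Of 51 oxidative phosphorylation genes 30 fell (31 adjusted over the list alone; median -0.19, adjusted p = 2.37e-06, adjusted p = 0.442 with an estimated correlation), with UQCR-11 at -0.74. Of 18 ecdysone response genes 10 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.46, adjusted p = 0.0235, adjusted p = 0.332 with an estimated correlation), the riser being spok (6.81 ± 0.65), a gene of ecdysone synthesis, and Eip74EF standing at -0.91. Of 35 piRNA pathway genes 10 fell and 3 rose (the same numbers adjusted over the list alone; median -0.13, adjusted p = 0.0235, adjusted p = 0.486 with an estimated correlation), with the Piwi-family gene AGO3 at -1.80 ± 0.31 (adjusted p = 5.29e-05) and cuff, which acts at piRNA clusters, at 1.12 ± 0.14. In fertile mutants AGO3 stood at -2.19 to -1.14 with NP6070 and at -0.23 to 0.11 without it.

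Some genes of the stress and immune lists rose in sterile ovaries. As a class these had higher muscle (median 3.87) and hemocyte markers (median 1.14), though NP6070/NP6070 did not. Of 17 heat shock genes 9 rose and 2 fell (10 and 2 adjusted over the list alone; median 1.53, adjusted p = 0.0101, adjusted p = 0.332 with an estimated correlation), with the small chaperone gene Hsp23 at 3.01 ± 0.29. Of 12 immune genes 6 rose (7 adjusted over the list alone; median 1.42, adjusted p = 0.0101, adjusted p = 0.312 with an estimated correlation), with nec, a serpin gene of the Toll pathway, at 3.41 ± 0.39. Of 19 apoptosis and stress genes 11 rose and 2 fell (the same numbers adjusted over the list alone; median 0.39, adjusted p = 0.0141, adjusted p = 0.312 with an estimated correlation), with the cell death gene rpr at 2.30 ± 0.39. By genotype rpr was above controls in fertile mutants too, at 0.92 to 2.41 beside 1.23 to 3.78 in sterile mutants. In early germline genes 5 of 17 rose and 3 fell (the same numbers adjusted over the list alone; median 0.01, adjusted p = 0.596), with the differentiation factor bgcn at 3.17 ± 0.29 (adjusted p = 2.28e-08) and otu at -0.68. In meiosis genes 8 of 23 rose and 2 fell (the same numbers adjusted over the list alone; median 0.10, adjusted p = 0.173), with the cohesion genes sunn at 3.23 ± 0.39 and ord at 3.27 ± 0.44.

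The remaining lists did not pass camera in this comparison. In sex determination genes 4 of 13 rose (4 adjusted over the list alone; median -0.04, mean 0.37, adjusted p = 0.596), with dsx, the switch gene of somatic sex, at 1.76 ± 0.35 and chinmo, which maintains male identity in testis soma, at 3.15 ± 0.40. Heterochromatin proteins gave 2 risers and 9 fallers of 26 (3 and 9 adjusted over the list alone; median -0.12, adjusted p = 0.0567), with stwl at 0.57 and Su(var)3-7 at -0.38. Ovarian soma genes gave 7 risers and 7 fallers of 22 (the same numbers adjusted over the list alone; median 0.01, while the test's direction was down, adjusted p = 0.896), with Fas3 at 1.81 and Mmp2 at 2.36. Testis-enriched genes gave 4 risers and 1 faller of 8 (the same numbers adjusted over the list alone; median 0.13, adjusted p = 0.442). Signalling genes of the JAK-STAT and BMP pathways gave 6 risers and 3 fallers of 16 (7 and 3 adjusted over the list alone; median 0.16, adjusted p = 0.316), with upd3 at 2.08. Antiviral RNAi genes gave 2 risers of 9 (1 adjusted over the list alone; median 0.05, adjusted p = 0.896), with loqs at 0.41. Both tested histone genes rose (2 adjusted over the list alone; median 2.07), and 2 genes were too few for a list test. Chromosome 4 genes gave 18 risers and 31 fallers of 75 (median -0.16, mean 0.38, adjusted p = 0.451) and pericentromeric genes 42 risers and 72 fallers of 192 (median -0.10, mean 0.33, adjusted p = 0.0846). The sets for X, 2L, 2R, 3L and 3R each had an adjusted p of 0.669, with the mean and the test differing in sign for the 4 autosomal arms, and the single tested Y gene did not pass. Outside the lists the largest rise was that of Sox21b, a Sox transcription factor gene (7.73 ± 1.24, adjusted p = 2.11e-05), and the largest fall that of Ilp7, an insulin-like peptide gene (-3.82 ± 0.58, adjusted p = 1.24e-05). By genotype, Sox21b stood at 8.696 to 9.694 in sterile mutants with KG00226 and at 1.868 to 3.614 in the other sterile mutants. In fertile mutants Sox21b stood at 2.025 to 6.538 with KG00226 and at -1.717 to 0.4757 without it.

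Fertile mutants were compared with controls, which all carry w1118, to ask what differs when eggs are still made. Transposable elements rose here too: 67 of 117 families (80 with 1 lower, adjusted over the list alone), with a median of 1.33 that was positive in 7 of 7 genotypes (0.64 to 2.11). The telomeric elements led, with HETA at 6.02 ± 0.74 (adjusted p = 1.54e-05), TAHRE at 5.93 ± 0.63 and TART at 5.88 ± 0.62 (adjusted p = 2.23e-06). The list passed camera (adjusted p = 9.91e-66; adjusted p = 0.00321 with an estimated correlation). Ribosomal protein genes passed as a list with a median of -0.26, though 1 of 81 fell by itself (14 adjusted over the list alone; adjusted p = 1.46e-22, adjusted p = 0.786 with an estimated correlation). Their median was -0.65 in NP6070/KG00226, -0.52 in NP6070/sov2 and -0.37 in sov2/NP6070, and -0.12 to 0.02 in the other 4 genotypes. Oxidative phosphorylation genes passed with a median of -0.16 and 6 of 51 falling (19 adjusted over the list alone; adjusted p = 6.87e-14, adjusted p = 0.786 with an estimated correlation). The chorion median was -0.45 (adjusted p = 0.158), the vitelline membrane median -0.26 (adjusted p = 0.536), the muscle median -0.15 (adjusted p = 0.52) and the hemocyte median -0.48 (adjusted p = 0.106). In all 332 genes changed, of which 114 fell. The largest falls outside the lists were those of CG11700 (-3.34 ± 0.48), CG7408 (-2.01) and modSP (-1.94), a protease gene upstream of Toll. By genotype, CG11700 stood at -3.50 to -2.465 in all mutants without sovEA42 or sovML150, fertile or sterile. It stood at 0.11 to 0.43 in the sterile mutants with either of those alleles. The number of changed genes was 191 without replicate 1 (52 falling) and 215 without NP6070/KG00226 (54 falling).

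Sterile and fertile mutants carry overlapping sets of alleles, and they were set against each other to ask what differs between the classes. All sterile genotypes except NP6070/NP6070 carry Dfsov, sovEA42 or sovML150, which no fertile mutant carries. Sterility therefore cannot be told apart from those alleles and their chromosomes. Against controls, NP6070/NP6070 had medians of 3.23 for elements and -1.57 for the chorion. Its medians were 0.04 for muscle, -0.38 for hemocytes, 0.20 for the vitelline membrane and -0.02 for heat shock. Of 117 elements 94 were higher in the sterile genotypes (98 adjusted over the list alone; median 1.55, adjusted p = 8.72e-29, adjusted p = 0.0895 with an estimated correlation), while element counts per ERCC count differed by -0.85, as given above. Of 17 chorion genes 14 were lower (17 adjusted over the list alone; median -2.32, adjusted p = 1.85e-10, adjusted p = 0.36 with an estimated correlation). Vitelline membrane genes had a median of -1.18 with 3 of 13 lower (1 adjusted over the list alone; adjusted p = 4.46e-05, adjusted p = 0.383 with an estimated correlation), and 3 of 4 yolk genes were lower (4 adjusted over the list alone; median -0.89, adjusted p = 0.0261, adjusted p = 0.387 with an estimated correlation). All 20 muscle genes were higher (20 adjusted over the list alone; median 3.93, adjusted p = 3.73e-19, adjusted p = 0.272 with an estimated correlation), as were 7 of 11 hemocyte genes (7 adjusted over the list alone; median 1.76, adjusted p = 8.36e-05, adjusted p = 0.383 with an estimated correlation), and the largest differences were those of Lsp2 (7.59 ± 1.18) and Hml (6.65 ± 0.74). Heterochromatin proteins had a median of -0.19 with 12 of 26 lower and 1 higher (13 and 1 adjusted over the list alone; adjusted p = 0.00109, adjusted p = 0.431 with an estimated correlation). Oocyte and maternal genes had a median of -0.33 with 17 of 26 lower (20 adjusted over the list alone; adjusted p = 6.69e-07, adjusted p = 0.272 with an estimated correlation). Neuronal, heat shock and immune lists were higher, with medians of 1.03, 1.39 and 1.19 (adjusted p = 0.000611, 0.0206 and 0.0216; adjusted p = 0.23, 0.387 and 0.383 with an estimated correlation). Replication and ecdysone response lists were lower, with medians of -0.32 and -0.34 (adjusted p = 8.36e-05 and 0.0104; adjusted p = 0.431 and 0.367 with an estimated correlation). Pericentromeric genes had 59 of 192 lower and 31 higher (62 and 32 adjusted over the list alone; median -0.13, mean 0.07, adjusted p = 0.00684, adjusted p = 0.524 with an estimated correlation). In all 3016 genes differed, 1812 higher and 1204 lower in sterile mutants.

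**Figure D3:**
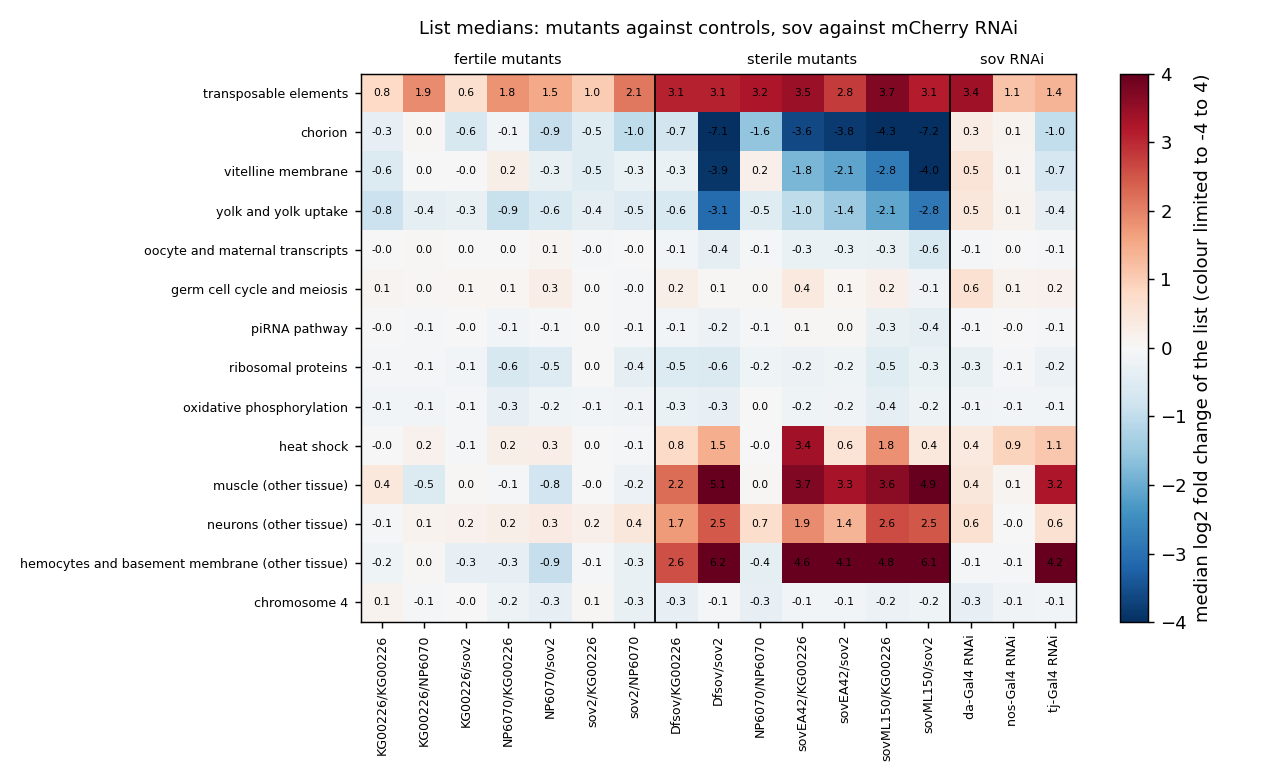
Median log2 change of 14 gene lists (vertical axis) in each of the 7 fertile and 7 sterile mutant genotypes against the 10 controls and in the 3 RNAi comparisons (horizontal axis); colour runs from -4 to 4 on the log2 scale. Transposable elements are above 0 in all 14 mutant genotypes (0.64 to 3.71), while the muscle median runs from 0.04 to 5.10 over the sterile genotypes.

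The sterile and fertile comparisons share the 10 control genotypes, which by itself makes their changes correlate. Of the genes that rose in fertile mutants, 182 also rose in sterile mutants (53.6 by chance), and of the 114 that fell in fertile mutants, 77 also fell (22.6 by chance). Across genes, which are not independent, r was 0.436 and the covariance 0.249. Simulated groups with no change gave a mean r of 0.411 and a highest of 0.449, so r with shared controls carries no information, with a covariance of at most 0.0226 and 0 shared calls. With the controls divided at random between the comparisons (10 divisions), r was 0.388 on average (0.277 to 0.455), the covariance was 0.29 on average (0.207 to 0.324), and 70.3 shared risers and 11.6 shared fallers were found on average.

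With da-Gal4, which drives the hairpin in all cells, the question was whether lowering sov throughout the animal alters the ovary as the alleles do. Of 96 transposable elements 80 rose (84 adjusted over the list alone), with a median of 3.38, also 3.38 with the 5 families absent from the mCherry libraries set at their bounds. MDG3 rose by 9.93 ± 0.32 (adjusted p = 5.79e-14), BATUMI by 9.17 ± 0.37 and Gypsy12 by 7.26 ± 0.32, and TART_B1 was at least 98-fold higher. The list passed camera (adjusted p = 3.52e-96; adjusted p = 0.00559 with an estimated correlation). Meiosis genes rose as a list, 9 of 19 up and 2 down (11 and 2 adjusted over the list alone; median 0.59, adjusted p = 0.0116, adjusted p = 0.0822 with an estimated correlation), with the synaptonemal complex genes corolla at 2.68 ± 0.28 and c(3)G at 1.19, and c(2)M at -1.04. Of 16 heat shock genes 5 rose (5 adjusted over the list alone; median 0.39, adjusted p = 0.0165, adjusted p = 0.937 with an estimated correlation), with Hsp23 at 4.03 ± 0.31. The chorion median was 0.30 (adjusted p = 0.449) and the vitelline membrane median 0.52 with 3 of 13 genes lower (3 adjusted over the list alone; adjusted p = 0.991), so the eggshell lists did not pass. Of 20 muscle genes 4 rose (6 adjusted over the list alone; median 0.44, adjusted p = 0.0912).

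Single genes of the germline changed as well with da-Gal4. AGO3 fell by 2.66 ± 0.33 on the log2 scale (adjusted p = 1.05e-05) among piRNA pathway genes, of which 5 of 35 fell and 3 rose (the same numbers adjusted over the list alone; median -0.06, adjusted p = 0.783). The translational regulator orb stood at -0.85 ± 0.15 among oocyte genes, of which 6 of 26 fell and 2 rose (the same numbers adjusted over the list alone; median -0.09, adjusted p = 0.236). RpS10a, which has a paralogue expressed in most tissues, rose by 4.57 ± 0.59, and blanks, a gene of the testis, by 5.46 ± 0.66. Heterochromatin proteins had 9 of 26 up (10 adjusted over the list alone; median 0.18, adjusted p = 0.0507), with HP4 at 0.64 and wde, a partner of the H3K9 methyltransferase Egg, at 0.52; under upper-quartile scaling the list passed (adjusted p = 0.0404). Ribosomal protein genes had a median of -0.28 with 2 up and 2 down of 81 (1 up adjusted over the list alone; adjusted p = 0.00133, adjusted p = 0.995 with an estimated correlation), and oxidative phosphorylation genes -0.14 with 4 of 51 down (1 adjusted over the list alone; adjusted p = 0.0348, adjusted p = 0.995 with an estimated correlation). The gene gNacalpha was at least 443-fold higher (adjusted p = 1.46e-08) and the synaptotagmin gene Syt4 at least 68.7-fold lower. In all 1622 of 7700 genes changed, 774 up and 848 down. The count was 944 without mCherry replicate 3, 987 without sov replicate 1, and 785 when the 6 da-Gal4 libraries were fitted alone.

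Chromosome 4 genes were lower with da-Gal4 sov RNAi. Of 69 tested, 29 fell and 3 rose (31 and 4 adjusted over the list alone; median -0.34, adjusted p = 1.48e-08, adjusted p = 0.149 with an estimated correlation). Pericentromeric genes gave 45 fallers and 18 risers of 165 (49 and 19 adjusted over the list alone; median -0.11, mean 0.03, adjusted p = 0.000128, adjusted p = 0.149 with an estimated correlation).

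With nos-Gal4, which drives in germ cells, the question was what the germline contributes. Of 96 elements 27 rose (45 with 1 lower, adjusted over the list alone), with a median of 1.14, or 1.07 with 3 families at their bounds. HETA rose by 9.12 ± 0.42 (adjusted p = 1.53e-11), TART by 8.31 ± 0.33 (adjusted p = 4.31e-12), TAHRE by 6.28 ± 0.29 and MDG3 by 6.20 ± 0.34. The list passed camera (adjusted p = 3.32e-46; adjusted p = 0.0533 with an estimated correlation). Of 16 heat shock genes 3 rose (7 adjusted over the list alone; median 0.88, adjusted p = 1.53e-06, adjusted p = 0.295 with an estimated correlation), with Hsp23 at 2.58 ± 0.24. Chromosome 4 genes had a median of -0.14 with 10 of 69 down and 1 up (15 and 1 adjusted over the list alone; adjusted p = 2.91e-09, adjusted p = 0.201 with an estimated correlation), among them CG31999 (-2.95 ± 0.51) and CG31997 (-2.89 ± 0.37). In the piRNA pathway 2 of 35 rose (3 with 1 lower, adjusted over the list alone; median -0.01, mean 0.04, adjusted p = 0.647), nxf2, which acts in piRNA-guided silencing in the nucleus, at 0.77 and qin at 0.72. The chorion median was 0.14 (adjusted p = 0.647), the vitelline membrane median 0.10 (adjusted p = 0.992) and the muscle median 0.12 (adjusted p = 0.464). Syt4 was at least 49.9-fold lower. In all 202 genes changed, 118 up and 84 down. The count was 121 without mCherry replicate 1, 134 without sov replicate 1 and 123 without sov replicate 3.

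With tj-Gal4, which drives in the ovarian soma, the question was what somatic cells contribute. Of 96 elements 40 rose (49 adjusted over the list alone), with a median of 1.36, or 1.34 with 1 family at its bound. ZAM rose by 6.61 ± 0.29 (adjusted p = 3.06e-11), Gypsy by 5.67 ± 0.29 and I_DM by 4.91 ± 0.50. The list passed camera (adjusted p = 7.35e-18), and its adjusted p was 0.315 with an estimated correlation. Summed element counts per ERCC count overlapped between the sov and mCherry libraries of this driver, as given above. Of 20 muscle genes 19 rose (20 adjusted over the list alone; median 3.22, adjusted p = 3.96e-87, adjusted p = 0.000591 with an estimated correlation), with bt, which encodes a giant sarcomere protein, at 3.39 ± 0.20. Of 13 hemocyte and basement membrane genes 8 rose (8 adjusted over the list alone; median 4.16, adjusted p = 2.14e-15, adjusted p = 0.0252 with an estimated correlation), with Ppn at 4.53 ± 0.25 and Hml at 4.76. Vitelline membrane genes had a median of -0.68 with 3 of 13 down (11 adjusted over the list alone; adjusted p = 7.03e-05, adjusted p = 0.315 with an estimated correlation) and chorion genes -0.98 with 6 of 17 down (8 adjusted over the list alone; adjusted p = 0.000233, adjusted p = 0.475 with an estimated correlation), with yellow-g2 at -1.16.

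Further groups moved with tj-Gal4 beside the rise of muscle and hemocyte markers. Genes of sperm storage and oviduct gave 3 risers of 7 (3 adjusted over the list alone; median 0.53, adjusted p = 0.0203, adjusted p = 0.315 with an estimated correlation), with the Hox genes abd-A at 3.20 and Abd-B at 3.18. Heat shock genes gave 5 risers of 16 (7 adjusted over the list alone; median 1.07, adjusted p = 0.0305, adjusted p = 0.523 with an estimated correlation), with Hsp23 at 3.26. The nuclear piRNA factor piwi was lower by a small amount (-0.34 ± 0.09, adjusted p = 0.0118). The sex determination gene chinmo rose by 2.35 and the cohesion gene ord by 2.99. Ribosomal protein genes had a median of -0.23 while the 2 that passed rose (2 adjusted over the list alone; adjusted p = 7.03e-05, adjusted p = 0.672 with an estimated correlation), and oxidative phosphorylation genes had a median of -0.12 with 1 of 51 down (adjusted p = 0.00591, adjusted p = 0.66 with an estimated correlation). Outside the lists Cyp4p2, a cytochrome P450 gene, was at least 137-fold higher, and Syt4 fell by 7.07 ± 0.49. In all 912 of 7700 genes changed, 717 up and 195 down. The count was 681 without sov replicate 2, and 111 genes fell without mCherry replicate 2.

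The difference between the germline and the somatic effect was tested directly. Elements divided in both directions, 8 of 96 with a larger change under nos-Gal4 and 11 with a larger change under tj-Gal4 (10 and 14 adjusted over the list alone; median -0.11, mean 0.04, adjusted p = 0.653 for the list as a whole). The telomeric elements were on the nos side, with differences of 9.25 ± 0.52 for HETA, 7.71 ± 0.74 for TART and 6.55 ± 0.61 for TAHRE, and ZAM on the tj side at -6.23 ± 0.78. Muscle genes differed by a median of -3.16, with 19 of 20 on the tj side (20 adjusted over the list alone; adjusted p = 5.71e-80, adjusted p = 0.000715 with an estimated correlation). The hemocyte median was -3.18, with 5 of 13 on the tj side (6 adjusted over the list alone; adjusted p = 1.29e-06, adjusted p = 0.251 with an estimated correlation). The vitelline membrane median was 0.85 (adjusted p = 7.93e-05, adjusted p = 0.407 with an estimated correlation) and the chorion median 0.79 (adjusted p = 6.27e-05, adjusted p = 0.443 with an estimated correlation). For sov itself the difference was -0.44 ± 0.16 (adjusted p = 0.151). In all 375 genes differed, 53 on the nos side and 322 on the tj side. The count was 238 without nos-Gal4 mCherry replicate 2, 249 without nos-Gal4 sov replicate 1 and 245 without tj-Gal4 sov replicate 2.

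**Figure D4:**
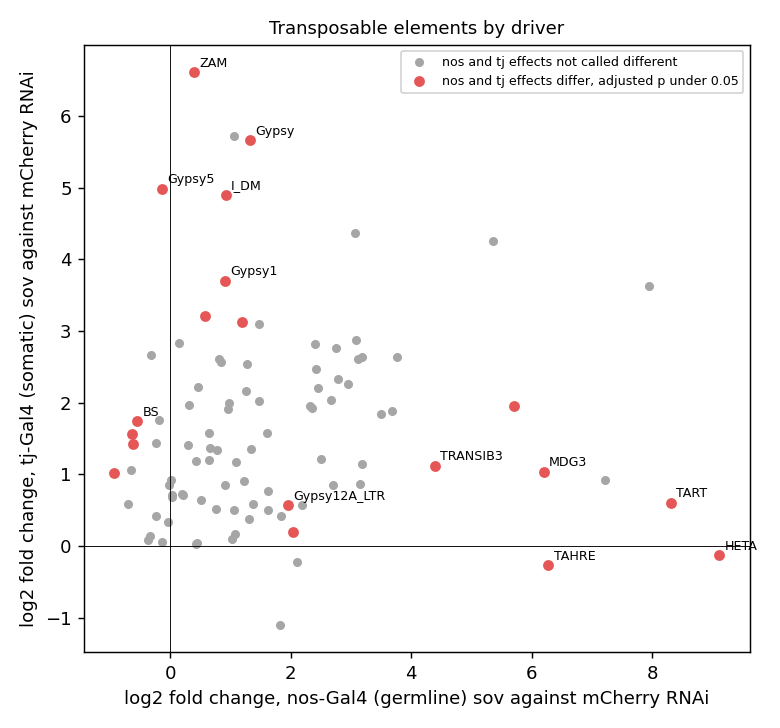
Log2 change of each of 96 transposable elements with sov RNAi under nos-Gal4 (horizontal axis) and under tj-Gal4 (vertical axis); red points differ between the drivers at an adjusted p under 0.05 (19 elements). HETA (9.12 under nos-Gal4) and TART (8.31) lie on the nos side and ZAM (6.61 under tj-Gal4) on the tj side.

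Genes that changed with RNAi were then looked up among those that changed in sterile mutants, which have separate controls. The numbers by chance and the Fisher tests treat genes as independent, which they are not. Of 700 tj-Gal4 risers tested in both fits, 621 also rose in sterile mutants against 151 by chance. Muscle markers rose in both comparisons (median 3.22 with tj-Gal4 and 0.04 to 5.10 over the sterile genotypes), so shared risers need not be genes that sov acts on. For da-Gal4 282 risers were shared against 164 (one-sided Fisher's exact p = 5.41e-25), 77 of them transposable elements, and for nos-Gal4 67 against 23.7 (one-sided Fisher's exact p = 2.92e-19), 26 of them elements. Shared fallers numbered 290 against 179 for da-Gal4 (one-sided Fisher's exact p = 5.47e-21), 25 against 17.2 for nos-Gal4 (p = 0.0264, exact) and 107 against 40.9 for tj-Gal4 (p = 5.61e-26, exact). Between drivers, da and nos shared 91 risers against 11.9 by chance (one-sided Fisher's exact p = 2.85e-68), da and tj 170 against 72.1 (p = 1.18e-29, exact), and nos and tj 45 against 11 (p = 1.37e-17, exact). The 3 drivers share the sov hairpin stock, so overlaps between them include any effect of that stock.

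The deficiency heterozygote was compared with w1118/w1118 to ask what differs with 1 copy of sov and its neighbours. With 1 genotype on each side, the differences include any from the background of the deficiency stock. Eggshell genes were lower as lists: the vitelline membrane median was -0.48 with 4 of 13 down (6 adjusted over the list alone; adjusted p = 2.82e-08, adjusted p = 0.698 with an estimated correlation) and the chorion median -0.63 with 2 of 17 down (8 adjusted over the list alone; adjusted p = 5.13e-07, adjusted p = 0.698 with an estimated correlation). Transposable elements had a median of 0.16 with 1 of 27 up (1 adjusted over the list alone; adjusted p = 0.34). Oxidative phosphorylation genes had a median of 0.08 with 2 of 51 up (3 adjusted over the list alone; adjusted p = 0.0127, adjusted p = 0.826 with an estimated correlation), and pericentromeric genes -0.11 with 5 of 147 down and 1 up (11 and 1 adjusted over the list alone; adjusted p = 0.0202, adjusted p = 0.915 with an estimated correlation). Of the genes tested within 50 kb of sov, CG3168 fell by 1.53 ± 0.21 on the log2 scale (adjusted p = 0.00246) and lncRNA:CR43496 by 2.01 ± 0.35 (adjusted p = 0.00982; 0.0518 without w1118/w1118 replicate 3). The 6 others there (Coq7, CG14441, RpL17, pod1, Nf-YC and C3G) lay between -0.12 and 0.27 and did not pass. The largest changes were those of Cyp4p2 (at least 99.3-fold higher), Culd (4.36 ± 0.18) and CG42857 (-5.40 ± 0.31). Cyp4p2 also rose with sov RNAi under all 3 drivers. In all 275 of 7245 genes changed, 104 up and 171 down; the count was 137 without w1118/w1118 replicate 2 and 105 without replicate 3.

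The labels write 6 pairs of genotypes with the same alleles in opposite order and do not say what the order means. Tested at once, the 6 pairs gave 2233 of 7764 genes that differed in at least 1 pair. RpL30, a ribosomal protein gene, had the smallest p (adjusted p = 7.34e-07), with log2 differences of 1.59 between KG00226/NP6070 and NP6070/KG00226 and -0.67 between NP6070/w1118 and w1118/NP6070. The genes that differed included 48 of 80 ribosomal protein genes, 15 of 21 replication genes, 12 of 26 heterochromatin proteins, 19 of 51 oxidative phosphorylation genes, 11 of 35 piRNA pathway genes, 10 of 20 muscle genes, 7 of 9 hemocyte genes and 17 of 95 elements, and no list test was run over the pairs. For sov the largest difference was -0.52, between KG00226/NP6070 and NP6070/KG00226 (adjusted p = 0.00078 over the 6 pairs; 0.0949 without replicate 2). Single pairs gave from 11 genes (sov2/w1118 and w1118/sov2) to 1284 (NP6070/w1118 and w1118/NP6070). The count over the 6 pairs was 1275 without replicate 1, 202 without replicate 2 and 821 without replicate 3.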

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

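Among the tests in this part, those on late egg chambers, on a few abundant elements, on the background of the hairpin stocks and on a swap with a da-Gal4 sov RNAi library were chosen only after the result was seen.

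Transposable element RNA was higher with da-Gal4 sov RNAi by a median of 3.38 on the log2 scale, and loss of late egg chambers could raise the share of RNA that stays. The chorion genes, transcribed in late follicle cells, argue against this, since their median change was 0.30 with da-Gal4. A few abundant elements did not carry the pattern, since the median over the elements without the 10 that held 84.3% of element counts was 3.24, and scaling of the libraries did not make it, since the median change per ERCC count was 2.96 and the lowest sov RNAi library held 11.3 times the element counts per ERCC count of the highest mCherry library. A difference between the hairpin stocks, which the drivers share, did not make the whole rise, since the element share was at least 20.1 times higher with da-Gal4 (lowest sov RNAi over highest mCherry library) and at most 5.45 times higher with tj-Gal4. With RNAi alone, a part of the size seen with tj-Gal4 (median 1.36) cannot be told apart from such a difference, since all drivers share these stocks. In mutants, which carry no hairpin, the element median was 2.80 to 3.71 over the sterile genotypes and 0.64 to 2.11 over the fertile ones. Mutants and controls differ in stock background too. Derepression of many elements when sov is lowered in the whole animal stays a hypothesis.

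Chromosome 4 genes were lower with sov RNAi, by a median of -0.34 with da-Gal4 (56 of 69 genes, against 48.1% of other genes) and of -0.14 with nos-Gal4 (52 of 69 genes). Expression level and gene length, da-Gal4 and nos-Gal4 alike, do not account for it, since 0 of 10000 random lists matched on both had a median as low for either driver. With tj-Gal4 the median was -0.10, with 45 of 69 genes lower, also below all 10000 matched random lists, while the mean was 0.13. A difference between the hairpin stocks may lower such genes with every driver, and RNAi alone cannot tell it apart from an effect of sov. The sov and mCherry hairpins differ in stock. The camera test of nos against tj gave an adjusted p of 0.00108 with a preset and 0.495 with an estimated correlation. In mutants, which carry no hairpin, the chromosome 4 median was -0.34 to -0.06 over the 7 sterile genotypes. It was -0.33 to 0.13 over the 7 fertile ones, 2 of them above 0. The set did not pass camera in sterile mutants, and mutants and controls differ in stock background too. Chromosome 4 is rich in heterochromatin, and an effect of sov on its genes is among the open explanations.

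In the control genotype KG00226/w1118, replicate 3 held 0.451% transposable element counts among its gene and element counts, against 0.0379% in the lowest replicate of that genotype. A mixture with da-Gal4 sov RNAi is a candidate explanation: 23 other genes that are high in that RNAi group stood at the level of a mixed share of 0.398 (interquartile range 0.289 to 0.616), beside 0.351 for 29 elements (0.295 to 0.376). A swap with a da-Gal4 sov RNAi library alone was excluded by the same 0.398, since it needs a share near 1. Other sources gave shares as high or higher, most from fewer genes, such as KG00226/NP6070 (1.05 over 9 genes and 0.402 over 6 elements), sov2/KG00226 (0.87 over 3 genes and 0.781 over 7 elements) and NP6070/KG00226 (0.583 over 13 genes and 0.618 over 9 elements). Their interquartile ranges over genes were wide: -0.0105 to 1.28, 0.437 to 1.13 and -0.006 to 0.974 in the same order. The element share of 0.451% lay outside the libraries of KG00226/NP6070 (0.758% to 0.981%), sov2/KG00226 (0.218% to 0.372%) and NP6070/KG00226 (1.02% to 1.82%). It lay within those of NP6070/sov2 (0.442% to 0.606%). That source gave 1.32 over 5 genes (interquartile range 0.0762 to 1.37) and 0.388 over 10 elements. Shares for nos-Gal4 sov RNAi were 0.338 over 13 genes and 0.392 over 7 elements. The source was therefore not fixed, and a mixture, or a swap with another sample, stays open. No biological explanation was tested, since the design names nothing that sets this replicate apart.

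ERCC spike-in RNA took 0.0612% ± 0.0358 of gene and element counts in the 7 sterile genotypes, against 0.0171% ± 0.00513 in the 10 controls (exact two-sided permutation p = 0.000309, adjusted over 3 comparisons 0.000874) and 0.013% ± 0.00255 in the 7 fertile mutants (exact permutation p = 0.000583, adjusted 0.000874). With tj-Gal4 it took 0.0276% to 0.0417% of gene counts in the sov RNAi libraries and 0.00894% to 0.0148% in the mCherry libraries, while these ranges overlapped with da-Gal4 and nos-Gal4. Per 100 ERCC counts the tj-Gal4 sov RNAi libraries held 268.7, 659.5 and 316.9 element counts and the mCherry libraries 231.7, 373 and 347.4, so that the higher element share with tj-Gal4 was not separated on this scale. These counts are outside the gene comparisons.

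The effects of nos-Gal4 and tj-Gal4 differed for 375 genes and for the lists of muscle (adjusted p = 5.71e-80), hemocytes and basement membrane (1.29e-06), chorion (6.27e-05), vitelline membrane (7.93e-05), ribosomal proteins (0.0269) and chromosome 4 (0.00108), all with the preset correlation. With an estimated correlation only the muscle list passed (adjusted p = 0.000715), and the adjusted p was 0.251 for hemocytes and basement membrane, 0.443 for chorion, 0.407 for vitelline membrane, 0.893 for ribosomal proteins and 0.495 for chromosome 4.

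Over sov levels, element shares and list medians, 5 of 76 groups tested had a genotype far from the others, where chance gives about 1 in 20. All 5 were among the 35 list medians of the fertile genotypes, against 0 of the 35 of the sterile genotypes. NP6070/sov2 stood apart for ovarian soma (-0.69, nearest -0.27), hemocytes and basement membrane (-0.92, nearest -0.34), early germline (0.143, nearest 0.049) and chromosome 2L (-0.024, nearest -0.00878), and NP6070/KG00226 for oxidative phosphorylation (-0.339, nearest -0.16).

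The samples were also divided in other ways to ask whether chance alone gives as many genes. Over 100 splits chance was excluded for sterile mutants against controls (3750 genes, highest other split 1785) and fertile mutants against controls (332, highest other 6). The real split ranked 1 in each. It also ranked 1 for allele order (2233, highest other 969). Those splits exchange libraries within a pair, where each order is 1 genotype. They cannot exclude chance differences between the genotypes of a pair. For sterile against fertile mutants 2 of 100 splits gave as many genes, the real one (3016) included. The higher one (3176) exchanged NP6070/NP6070 and KG00226/KG00226, which points to a structure of the samples. The count therefore does not single out the grouping by fertility, and these splits cannot exclude chance for it. For the nos and tj difference 4 of 100 splits gave as many as the real 375, the real one included. These splits exchange sov and mCherry libraries under both drivers, so an effect of 1 driver alone can rank the real split high. They cannot exclude chance for a difference between the drivers. The highest other (466) kept the real tj-Gal4 groups and mixed the nos-Gal4 groups. With 3 against 3 libraries the 10 splits are too few for a share under 0.05: the real and highest other counts were 1622 and 424 for da-Gal4, 202 and 0 for nos-Gal4, 912 and 0 for tj-Gal4, and 275 and 0 for the deficiency.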

How the results depend on the processing

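The fits without the libraries under 100000 counts and without KG00226/w1118 replicate 3 were chosen only after the data were seen. Counts stayed within 1.5 times the reported count under DESeq2 size factors, TMM without the yolk and eggshell lists and, where run, DESeq2's test (not run for allele order), upper-quartile scaling, limma voom and the fits without libraries under 2000000 counts, which exist neither for RNAi nor for the deficiency, where no library was that shallow. Upper-quartile scaling of the allele-order test was not run, since the library of 2110 counts gave offsets that were not finite. Without the libraries under 100000 counts the counts were 3752 (sterile), 332 (fertile), 3025 (sterile against fertile) and 2397 (allele order), and without KG00226/w1118 replicate 3 they were 3688, 347, 2935 and 2654. Without da-Gal4 sov replicate 3 the da-Gal4 count was 1951.

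With no filter on low counts, which tests more genes, the counts rose to 5853 (sterile), 4696 (sterile against fertile), 449 (nos-Gal4), 708 (nos against tj) and 789 (deficiency); the cause was not tested. With libraries as the unit, which replaces the spread between genotypes by that between libraries of a genotype, they were 5920, 2800 and 5646 for sterile against control, fertile against control and sterile against fertile, 5940, 2841 and 5653 with a replicate block, and 5914, 2776 and 5659 with the ERCC pool as a covariate. A replicate block gave 168 for the deficiency, and fits of 1 driver alone gave 785 for da-Gal4, 283 for nos-Gal4 and 955 for tj-Gal4; the cause was not tested. Leaving out libraries, replicates or genotypes, which leaves fewer samples, gave 191 to 411 for fertile against control, 944 to 1974 for da-Gal4, 121 to 158 for nos-Gal4, 238 to 422 for nos against tj, 105 to 298 for the deficiency and 202 to 2654 for allele order. The ranges were 3059 to 4450 for sterile against control, 2282 to 3931 for sterile against fertile and 681 to 866 for tj-Gal4.

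Of the list tests 57 passed with the preset and 6 with an estimated correlation, and of the chromosome sets 6 passed with the preset, 0 with an estimated correlation and 19 with fry, which asks another question. Named genes kept their direction in every fit except w in sterile mutants, at 2.53 in the reported fit and -0.77 to 2.80 over the genotypes left out, lowest without NP6070/NP6070. Over all alternatives a named gene lost its call in 245 cases, gained one in 93 and did neither in 7877. No scaling moved the median of all genes by 0.1 on the log2 scale. The 3 libraries under 100000 counts limit what their genotypes can show.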

Other observations

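Changes shared by the 3 drivers were 28 genes and 13 transposable elements that rose with da-Gal4, nos-Gal4 and tj-Gal4 alike, and 21 genes that fell. The elements included BATUMI, BLOOD, CIRCE, Copia1, Copia2, Gypsy12 and TIRANT. The genes that rose included Hsp23, a small heat shock protein gene, and those that fell included Syt4, a synaptotagmin gene, and jtb. All 3 sov RNAi groups carry the same hairpin stock, and these names were picked after the values were seen.

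Across the 96 elements, which are not independent of each other, changes with da-Gal4 followed those with nos-Gal4 (r = 0.766, rho = 0.783) more than those with tj-Gal4 (r = 0.102, rho = 0.153), and changes with nos-Gal4 and tj-Gal4 were nearly unrelated (r = 0.0279, rho = 0.147). In NP6070/NP6070, a sterile genotype, the element median was 3.23 while the medians were 0.04 for muscle, -0.38 for hemocytes, 0.20 for the vitelline membrane and -1.57 for the chorion.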
